A study of Solanum lycopersicum with 6 samples.

How the data were processed

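The data are RNA molecule counts from single shoot meristems of tomato (Solanum lycopersicum, cultivar M82-SP), collected while the plant passes from making leaves to making flowers. Each plant gave its only primary shoot meristem, so each meristem is a plant and is the replicate here. Morphology under a stereoscope assigned each meristem to a stage, per the labels' protocols: vegetative (VM), transition with progressive doming (TM0, TM1, TM2), late transition (LTM), early flower with a clear fork (EFM) and flower with sepal primordia (FM). Further stages recorded only in uf (TM2E) or only in s (LTM2, LTM3) entered no comparison with wild type.

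The authors captured polyadenylated RNA from each meristem on beads and made 3' tag libraries with MARS-seq, a plate-based method with unique molecular identifiers (UMIs), spreading each meristem over several wells, per the labels' protocols. The deposited counts are UMIs per gene summed over the wells of a meristem, per the labels' protocols. Bowtie2 is named in the submitters' processing notes with no version, and the genome build is not given in the sources used here, so no coordinates are printed and the chromosome is read from the identifier only. The other deposited columns used, unit other in the record of units, are text labels per meristem (genotype, plate, season, stage, age and leaf number). A second table of the authors holds the counts scaled to a constant sum and was not used.

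The UMI table has 34133 gene rows and 1103 meristems, of which 1257 rows merge several genes and 24889 carry a name or description from the authors' gene table. Column sums equalled the totals in the metadata for 1102 meristems. Well tables of 29 plates were compared with the UMI table on 1337 gene rows. On 21 plates every meristem matched exactly, and on 8 plates (66, 67 and 75 to 80) the UMI table was 1.46 to 1.65 times the sum of the wells. Unused wells on 4 plates held between 1.28% and 6.06% of the UMIs of a filled well. Genotypes were taken from the labels, which give the alleles s-n5568 and puchi-3b, the latter also for the triple mutant. In the group lob30_lob31, 89 meristems (plates 52, 66 and 67) carry a shorter label than the other 84, and the group joins both as the sample labels do. 3 sympodial meristems of wild type were left out, and 5 lob30_lob31 meristems without a stage entered no test, so 1100 meristems were kept. None of the identifiers looked up, a part of all gene rows, matched the RefSeq gene table, so names come from the authors' table and from the lists below. The identifiers of UF (Solyc09g005070), S (Solyc02g077390), PUCHI (Solyc01g067540) and LOB30 (Solyc01g091420) are named there, and LOB31 was not analysed here because no source used here ties it to an identifier.

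Total UMIs per meristem ranged from 100797 to 8869022. The counting of 3' tags without a stated use of strand cannot part overlapping genes on opposite strands, and rows that merge near-identical genes are named as shared where they appear.

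The main test was edgeR's quasi-likelihood test on UMI counts per meristem with TMM normalization and the filterByExpr filter on low counts. Genotype comparisons used stage as a covariate, over stages with at least 3 meristems in each genotype. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 and its change at least 1.5-fold. All adjusted p-values of genes below come from this test unless another is named. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. Levels are counts scaled to the TMM-adjusted library total (CPM) with the SD over meristems, computed here from the counts. Wild-type stage levels were scaled over wild type alone and levels of the mutated genes over all genotypes together, so wild-type values of the same gene differ slightly. Plates hold 1 genotype each, so genotype and plate are nested: limma's voom with plate as a random block, and sums per plate and stage tested with edgeR and DESeq2, were alternatives. P-values of the main test treat the meristems of a plate as independent.

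In wild type, each stage was compared with the one before it. A transient gene was higher (or lower) in the mean of TM2, LTM and EFM than in VM and also than in FM, both past the threshold. To follow transient genes in the mutants, they were chosen on a random part of the wild-type meristems (187) and tested against the others (189) at TM2, LTM and EFM. The parts were drawn within stage and not by plate, so both can hold meristems of the same plate. Fixed gene lists were tested with limma's camera with a preset correlation of 0.01 and again with an estimated correlation, with adjustment over all list tests. The lists were inflorescence and flowering regulators, floral organ identity MADS genes, genes of meristem maintenance, boundaries and axillary meristems, photosynthesis (also a marker of leaf tissue left on the meristem), histones and mitotic cyclins, cytosolic ribosomal proteins, the LBD family, auxin, cytokinin, gibberellin, heat shock and late embryogenesis proteins, epidermis and cuticle, vascular and cell wall, trichome and wound, and the SBP-box family. The former 3 were fixed by identifier and the others by words in the gene description. A list of MADS-box genes by description kept 1 tested member and was not tested as a group.

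The genes to be named were fixed by rule: the mutated genes; up to 4 called members of each list with the largest absolute change; for each genotype comparison and the transient set, the 8 highest and 8 lowest among genes called both by edgeR and with plate as a random block, with at least 20 CPM in the higher group and an informative name; and for each stage step the 4 highest and 4 lowest with plate as a fixed block. Genes outside the rule are said to be chosen after their values were seen. The tests, lists, naming rule and the alternatives not called added were chosen before the data were examined.

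After the data were seen, a library score was added as an alternative covariate: the mean log2 CPM of 200 genes that were higher on wild-type plate 56 than on plates 55 and 57 to 59 of the same season, minus that of 200 genes that were lower, all at 50 CPM or more, centred on the wild-type mean. In the comparisons of genotypes, counts of calls with and without it leave out these genes; the wild-type stage steps and the comparisons between seasons or rounds keep them. Other added alternatives were the phase assigned by the authors in place of stage, the log2 of total UMIs as a covariate, single seasons or plates, and early stages for the transient genes. The planned score from the first principal component of 500 variable wild-type genes followed the library score (Spearman rho -0.946 across wild-type meristems) and not the order of stages (rho 0.0195), so it did not stand in for stage.

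The edgeR and voom tests were tested on simulated counts with 200 changed genes. At the sizes of s against wild type edgeR recovered 60.6% of 1.5-fold and 100% of 2-fold changes with 5 false calls among 9851 genes, and at those of puchi 47.7% and 100% with 5 false calls among 8968 genes. With a simulated plate effect of SD 0.3 on the log2 scale added to s against wild type, edgeR made 64 false calls, edgeR on sums per plate and stage 61, and the fit with plate as a random block 8. There the block recovered 77.6% of 2-fold changes and edgeR 97.0%, and without a plate effect the block made 34 false calls at the sizes of puchi. The effect was drawn for each gene on its own and does not stand for the real plates. Exchanging those of s and wild type called a median of 196.5 genes (highest 3578). The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and Python 3.11.15 with numpy, pandas and matplotlib.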

Results

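Transcripts were counted in 1100 single shoot meristems of tomato from 6 genotypes: 376 of wild type (WT, 15 plates), 241 of uf (9 plates), 144 of s (5 plates), 85 of puchi (3 plates), 173 of lob30_lob31 (6 plates) and 81 of puchi_lob30_lob31 (3 plates). UF (UNIFLORA) encodes a bHLH factor, S (COMPOUND INFLORESCENCE) the homeobox factor WOX9, PUCHI an AP2/ERF factor, and LOB30 and LOB31 are factors with a LATERAL ORGAN BOUNDARIES domain (LBD). According to the series' design text, such factors belong to a module that is switched on for a short time after the meristem is committed to flowering and before flower organs form, and the mutants were profiled to see what each loss changes in this course. The median total was 683044 UMIs per meristem in WT, 575468 in uf, 1001089 in s, 201039 in puchi, 369818 in lob30_lob31 and 197136 in puchi_lob30_lob31. In WT, 48 meristems were at VM, 88 at TM0, 58 at TM1, 31 at TM2, 54 at LTM, 57 at EFM and 40 at FM. Ages were recorded for 173 WT meristems (median 10 days after germination, range 8 to 12) and for 165 of uf (median 13, range 10 to 19). For lob30_lob31 there were 138 (median 11, range 9 to 24), with 50 meristems at 16 days and 9 at 24 days. In uf, meristems at LTM had a median of 10 leaves, against 8 in WT.

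The WT series asks which genes change as a meristem turns from vegetative growth to a flower. PUCHI and LOB30 described a sharp pulse. PUCHI stood at 2.50 ± 4.51 CPM at VM (SD, n = 48), 119 ± 177 at TM1 (n = 58), 150 ± 130 at TM2 (n = 31) and 44.0 ± 48.0 at FM (n = 40). LOB30 stood at 1.06 ± 2.08, 62.2 ± 114, 133 ± 105 and 22.3 ± 25.8 CPM at the same stages. TM5, a SEPALLATA-type MADS gene of the floral whorls, was at or below 1.64 CPM up to LTM and reached 14.3 ± 17.8 at EFM and 135 at FM. TMF, an ALOG factor that keeps meristems vegetative, declined from 560 ± 235 CPM at TM0 to 82 ± 150 at FM.

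**Figure D1:**
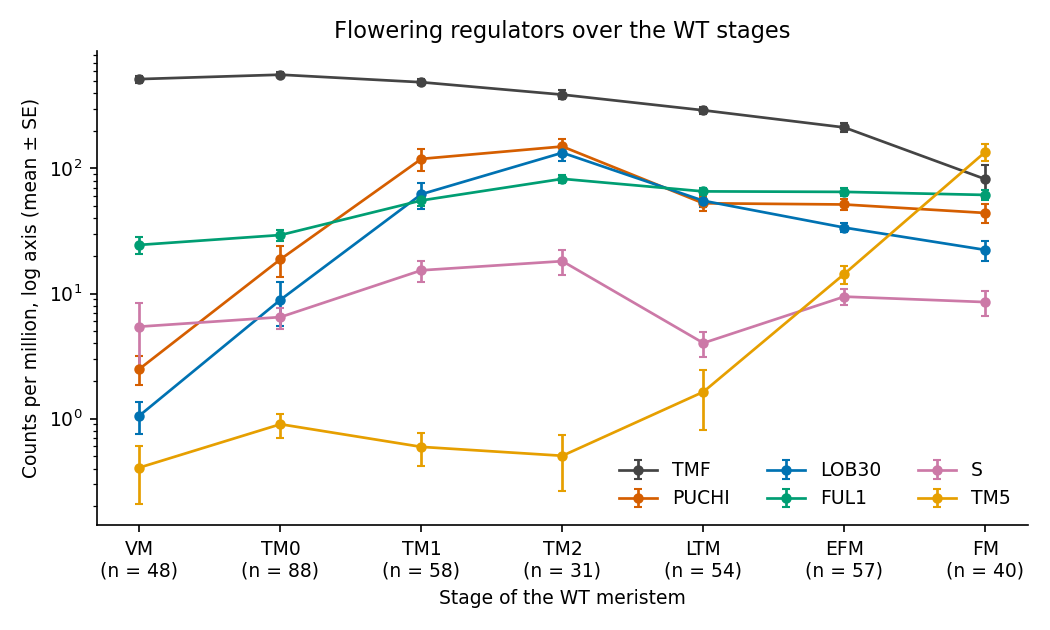
Mean level (CPM, log axis) of regulators at the 7 stages of WT meristems, with the standard error over meristems as bars. PUCHI and LOB30 peak at TM2, at 150 and 133 CPM, and TM5 rises last, to 135 at FM.

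From VM to TM0, LOB30 (log2 fold change 3.64 ± 0.68 SE, adjusted p = 0.00027) and PUCHI (3.23 ± 0.53, adjusted p = 7.2e-06) rose. With plate as a random block they were at 0.40 and 1.00, neither called, and without WT plate 54 the step called 5 genes. The row shared by MC (MACROCALYX) and RIN, MADS genes, rose by 1.66 ± 0.33. An asparaginase gene (Solyc04g078460) rose by 1.46 ± 0.28, rhizopuspepsin-4 (Solyc03g123670) by 1.14 ± 0.23, a cold shock protein (Solyc10g055250) by 1.00 ± 0.21 and a Myb factor (Solyc06g065100) by 0.96 ± 0.17. Chitinase (Solyc10g074440) changed by -1.96 ± 0.41 and a costars protein (Solyc11g044230) by -1.67 ± 0.36. Of 14 inflorescence and flowering regulators 3 rose and 1 fell (3 and 1 when adjusted over the list alone). The camera test of that list had an adjusted p of 0.027, and an adjusted p = 0.439 with an estimated correlation. SSP, a bZIP partner of florigen, changed by -0.76 ± 0.23, and CLV3, the peptide that limits stem cells, by -1.42 ± 0.27; neither passed with plate as a fixed block (-0.29 and -0.93). Among 53 photosynthesis genes 4 fell (5 when adjusted over the list alone), led by photosystem I gene Solyc08g013670 (-1.74 ± 0.33), and among 144 ribosomal protein genes 9 fell (10 over the list alone), led by Solyc06g007220 (-1.82 ± 0.44). In all, 58 genes rose and 399 fell of 9735 tested (n = 88 and 48). With plate as a fixed block the step called 61 genes, and its fold changes correlated with those between WT plate 56 and plates 55 and 57 to 59 (Spearman 0.605).

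From TM0 to TM1, LOB30 rose by a further 2.63 ± 0.29 (adjusted p = 5.0e-15) and PUCHI by 2.52 ± 0.27 (adjusted p = 1.4e-15). Of the 14 inflorescence regulators 7 rose (7 up and 1 down when adjusted over the list alone; camera adjusted p = 2.0e-06, and adjusted p = 0.0145 with an estimated correlation), among them MBP20, a FRUITFULL-clade MADS gene (1.24 ± 0.33), and S (0.91 ± 0.26). FUL2 (0.89 ± 0.20) and FUL1 (0.86 ± 0.17), of the same clade, are named after their values were seen. An AT hook protein (Solyc01g080960, 2.07 ± 0.24) and a glycine-rich protein (Solyc09g092700, 1.78 ± 0.25) rose beside them. In the LBD family 2 of 6 rose (3 when adjusted over the list alone), LOB30 and Solyc01g091400 (0.83 ± 0.15); camera gave an adjusted p = 0.00107, and adjusted p = 0.0562 with an estimated correlation. CLV3 changed by -1.65 ± 0.41, its receptor kinase FAB by -0.64 ± 0.18, a gibberellin receptor (Solyc07g040890) by -1.09 ± 0.18 and a gene annotated as nuclear transcription (Solyc12g009050) by -0.89 ± 0.17. BOP1, a BLADE-ON-PETIOLE gene, rose by 0.76 ± 0.18, which did not reach 1.5-fold with plate as a fixed block (0.58). Late embryogenesis protein Solyc09g008770 rose by 2.14 ± 0.25, 1 of 2 called among 40 heat shock and late embryogenesis genes, and PIN-type auxin efflux gene Solyc10g078370 by 0.79 ± 0.13. The step called 125 genes.

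From TM1 to TM2, bark storage protein Solyc08g066880 rose by 2.71 ± 0.25, leucine aminopeptidase Solyc12g010020 by 2.62 ± 0.33, polyphenol oxidase Solyc08g074683 by 2.37 ± 0.30 and arginase 2 (Solyc01g091170) by 2.29 ± 0.36. Of 7 trichome and wound genes 4 rose, polyphenol oxidase Solyc08g074680 by 2.77 ± 0.40 (camera adjusted p = 0.00298; adjusted p = 0.0788 with an estimated correlation). LOB30 rose by 1.09 ± 0.29 and the LBD gene Solyc02g085910 by 1.72 ± 0.28, 2 of 6 LBD genes (camera adjusted p = 0.0213; adjusted p = 0.212 with an estimated correlation). PUCHI moved by 0.33 ± 0.31 and was not called. The Myb factor LMI2 (Solyc05g048830) changed by -1.51 ± 0.23 and a GRF1-interacting factor (Solyc11g006230) by -1.10 ± 0.16. Of 21 epidermis genes 1 rose and 3 fell; lipid-transfer proteins went both ways (Solyc09g018010 1.85 ± 0.43 and Solyc10g075070 -1.33 ± 0.26). The step called 221 genes.

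From TM2 to LTM, PUCHI and LOB30 left their peak and stayed above VM, at 51.9 and 54.1 CPM at LTM. S changed by -1.95 ± 0.34 (adjusted p = 1.3e-05), PUCHI by -1.52 ± 0.31 and LOB30 by -1.27 ± 0.30, the 3 called members of the inflorescence list (4 when adjusted over the list alone; camera adjusted p = 0.000337, and adjusted p = 0.0788 with an estimated correlation). BOP2 (-1.22 ± 0.25) and BOP1 (-0.85 ± 0.23) fell among 9 genes of meristem maintenance and boundaries. Leucine aminopeptidases Solyc12g010030 (1.78 ± 0.34) and Solyc12g010020 (1.63 ± 0.26), asparagine synthase Solyc06g007180 (1.70 ± 0.26) and an auxin-repressed protein (Solyc03g006360, 1.48 ± 0.27) rose. Late embryogenesis protein Solyc03g116390 changed by -2.22 ± 0.34, glycine-rich protein Solyc09g092700 by -2.19 ± 0.35 and LBD gene Solyc01g091400 by -0.91 ± 0.19. The SBP-box gene Solyc07g062980, of the family that promotes flowering, rose by 0.97 ± 0.20. The step called 93 genes, and 175 with plate as a fixed block.

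From LTM to EFM, TM5 rose by 3.01 ± 0.32 (adjusted p = 4.8e-16), the called member of 2 floral organ identity genes tested (camera adjusted p = 0.00552; adjusted p = 0.0562 with an estimated correlation). A Dof zinc finger (Solyc02g065290, 1.83 ± 0.19), an epidermal patterning factor (Solyc03g121790, 1.73 ± 0.16) and a defensin (Solyc07g006380, 1.51 ± 0.21) rose, as did chlorophyll a/b-binding protein Solyc03g005780 (2.27 ± 0.28, at 32.4 ± 174 CPM at EFM; 1.2 with plate as a fixed block, and 0.66 with a random one, not called), 1 of 5 among 53 photosynthesis genes (camera adjusted p = 0.0214; adjusted p = 0.725 with an estimated correlation). MBP20 changed by -1.09 ± 0.31, J (JOINTLESS), a MADS gene that keeps the inflorescence indeterminate, by -0.79 ± 0.24 and the caffeic acid gene Solyc10g005060 by -1.70 ± 0.22. S (1.13 ± 0.32) and LYR (LYRATE, a JAGGED-type zinc finger; 0.81 ± 0.25) rose without a plate term only. From EFM to FM, TM5 rose by another 3.31 ± 0.19 (adjusted p = 3.2e-47), and TM6, a B-class MADS gene, by 0.77 ± 0.27, the latter without a plate term only. Isocitrate lyase (Solyc07g052480, 3.00 ± 0.16), a metallocarboxypeptidase inhibitor (Solyc07g007250, 2.91 ± 0.22) and a bHLH factor (Solyc04g076240, 2.78 ± 0.18) rose. TMF changed by -1.49 ± 0.18, an epidermal patterning factor (Solyc00g044350) by -1.73 ± 0.21, lipoxygenase A (Solyc08g014000) by -1.59 ± 0.22 and cytochrome P450 Solyc03g114940 by -1.52 ± 0.33. Photosynthesis genes rose as a group, 19 of 53 up and 1 down (camera adjusted p = 6.5e-16, and adjusted p = 0.0147 with an estimated correlation), for example Solyc07g063600 (1.44 ± 0.21) and Solyc12g044280 (1.13 ± 0.18). Of 60 histones and cyclins 6 rose (camera adjusted p = 9.3e-16; adjusted p = 0.212 with an estimated correlation). The SBP genes CNR (1.12 ± 0.13) and Solyc01g090730 (0.93 ± 0.19) rose, and 4 of 23 auxin genes fell, among them Auxin Response Factor Solyc01g096070 (-1.25 ± 0.18). The steps called 217 and 661 genes. WT meristems at FM come from 1 season only, so stage and season are partly joined there, and with plate as a fixed block the steps called 705 and 260 genes.

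Across the course, 92 genes were transiently high at TM2, LTM and EFM and 38 transiently low. LOB30 was 6.29 ± 0.52 above VM and 1.57 ± 0.29 above FM. PUCHI (5.07 ± 0.46 and 0.77 ± 0.28), FUL2 (0.73 ± 0.21 and 0.91 ± 0.22) and MBP20 (1.22 ± 0.34 and 0.97 ± 0.32) met the same definition, so 4 of the 14 inflorescence regulators were transient. The strongest others were lipoxygenase A (Solyc08g014000), which makes oxylipins (4.88 ± 0.33 and 1.66 ± 0.20), a glucan endo-1,3-beta-glucosidase (Solyc08g074390, 3.05 ± 0.21 and 1.66 ± 0.16), metallothionein Solyc01g112230 (2.20 ± 0.24 and 2.46 ± 0.24), the caffeic acid gene Solyc10g005060 (1.88 ± 0.25 and 2.67 ± 0.27) and anthranilate synthase Solyc12g010180, of the tryptophan pathway (1.42 ± 0.12 and 1.54 ± 0.13). Transiently low genes included a SAM-dependent methyltransferase (Solyc12g014500, -2.69 ± 0.25 and -3.03 ± 0.24), LMI2 (-1.84 ± 0.15 and -0.89 ± 0.16) and the gene described as UPSTREAM OF (Solyc04g054800, -1.47 ± 0.10 and -1.41 ± 0.11). In the middle stages 3 of 6 LBD genes and 5 of 7 trichome and wound genes were above VM (each with adjusted p = 0.0120 with an estimated correlation), and 30 of 53 photosynthesis genes were below FM (adjusted p = 0.00225 with an estimated correlation).

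The mutated genes check the labels where the altered part can be counted, and a 3' tag outside it checks nothing. PUCHI stood at 56.3 ± 103 CPM in WT (SD, n = 376), 1.03 ± 2.45 in puchi (n = 85) and 0.712 ± 2.04 in puchi_lob30_lob31 (n = 81). S stood at 8.63 ± 14.9 CPM in WT and 1.54 ± 2.04 in s (n = 107). It was also at 0.457 in uf, 1.45 in puchi and 1.37 in puchi_lob30_lob31, so a low level of S does not mark s alone. LOB30 was at 47.0 ± 81.2 CPM in lob30_lob31 (n = 168) against 38.5 ± 72.1 in WT, so its tag did not mark this genotype, and at 5.73 ± 10.2 in puchi_lob30_lob31. UF lay near the floor in each genotype, with 74 UMIs in 51 of 376 WT meristems and 19 UMIs in 11 of 214 uf meristems, and could not serve as a check.

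**Figure D2:**
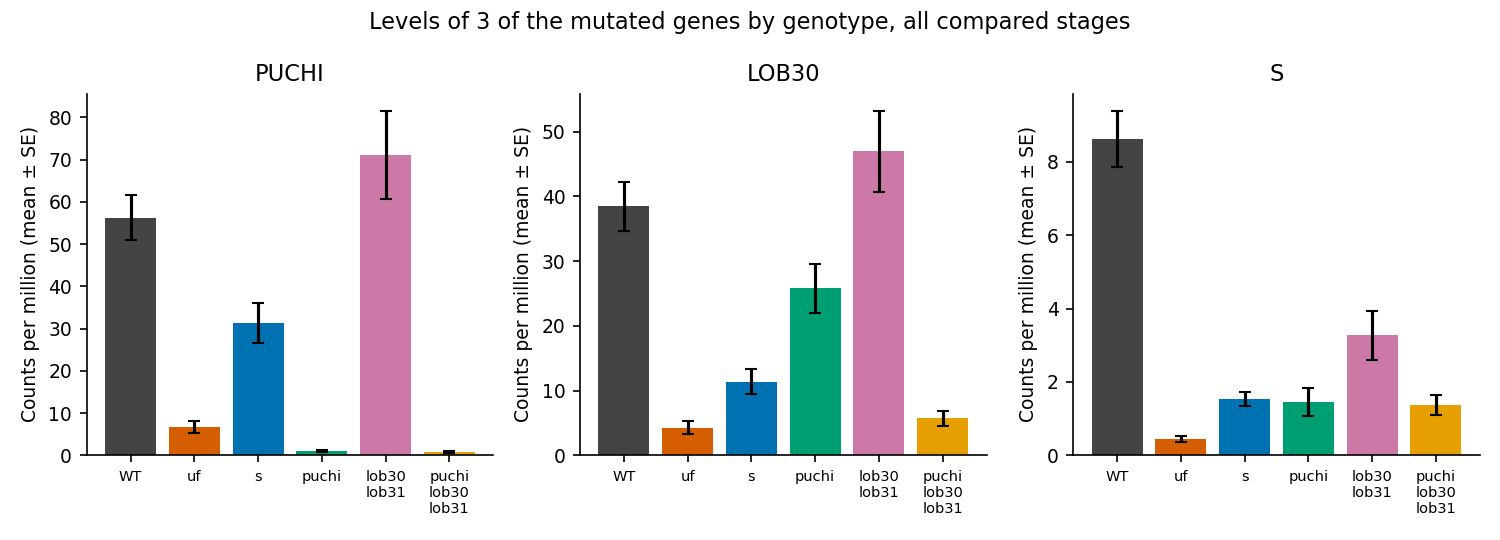
Mean CPM of the mutated genes in each genotype, with the standard error over meristems as bars. PUCHI is at 1.03 in puchi and 0.712 in puchi_lob30_lob31 against 56.3 in WT, and LOB30 is at 47.0 in lob30_lob31.

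Meristems of uf were compared with WT at matched stages to ask what loss of UNIFLORA, whose mutants form single flowers, changes in the course. Recorded ages of uf were 15 to 19 days at TM2 and LTM and 19 at EFM, against at most 12 days in WT. Age was not a covariate, so the uf results do not part genotype from plant age. Averaged over the stages, S was lower, at -3.75 ± 0.23 (adjusted p = 3.3e-50), LOB30 at -3.45 ± 0.21 (1.7e-47) and PUCHI at -3.37 ± 0.21 (1.0e-48), with 214 uf and 376 WT meristems. PUCHI averaged 6.65 ± 20.4 CPM in uf. By stage, on levels scaled over all genotypes together, it was at 2.93 CPM at TM1 and 1.37 at TM2, against 123 and 149 in WT, but at 42.6 against 51.9 at LTM. LOB30 was at 0.67 and 0.36 against 63.7 and 133, and at 31.6 against 54.1 at LTM. With plate as a random block the values were -2.30, -2.56 and -3.50, all called. Of 14 inflorescence regulators 3 rose and 5 fell, the same when adjusted over the list alone (camera adjusted p = 0.176). J was higher by 1.63 ± 0.15, not called with the plate block (0.33). SSP (1.40 ± 0.14), FUL1 (-1.25 ± 0.10) and FUL2 (-1.13 ± 0.11) are named after their values were seen; of these FUL1 kept its call with the block (-1.47). TM5 was lower, at -1.23 ± 0.30 (block -1.43). Of 9 meristem and boundary genes CLV3 rose (0.96 ± 0.17), without the block only, while TKN2, the SHOOT MERISTEMLESS-type factor, was at -0.38 ± 0.04, not called. Uncalled values were 0.46 ± 0.07 for TMF and -0.25 ± 0.05 for FA (FALSIFLORA, the LEAFY homologue).

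Outside the lists, a BED zinc finger (Solyc11g040105) was higher in uf by 2.06 ± 0.14, an HR-like lesion-inducing protein (Solyc03g005470) by 1.5 ± 0.09, transportin-3 (Solyc02g094620) by 1.42 ± 0.10 and an auxin canalization protein (Solyc09g065590) by 0.99 ± 0.07. In the summer of 2019, the season that uf shares with WT, Solyc03g005470 was at -0.75 and Solyc09g065590 at -0.093. Ribosomal proteins Solyc11g040220 (-2.33 ± 0.12) and Solyc06g066660 (-2.07 ± 0.08), the asparaginase gene Solyc04g078460 (-1.70 ± 0.13), a plasma membrane gene (Solyc08g081190, -1.66 ± 0.07) and cold shock protein Solyc10g055250 (-1.63 ± 0.10) were lower. The cytokinin-activating LOG genes moved apart, Solyc10g082020 by -1.30 ± 0.09 and Solyc11g069570 by 1.00 ± 0.13, with 2 up and 1 down among 15 cytokinin genes. Of 53 photosynthesis genes 11 rose, for example Solyc03g005780 (1.23 ± 0.15) and Solyc05g056050 (1.22 ± 0.09), with camera adjusted p = 0.000275 and adjusted p = 0.45 with an estimated correlation. None of the 11 kept its call with the plate block. Of 144 ribosomal protein genes 4 rose and 9 fell, such as Solyc05g026045 (-1.64 ± 0.09), with camera adjusted p = 7.5e-05 and adjusted p = 0.582 with an estimated correlation. D-type cyclins Solyc01g107730 (2.18 ± 0.15) and Solyc02g092980 (1.66 ± 0.15) were among 6 higher and 1 lower of 63 histones and cyclins, none of them with the block. Of 42 heat shock and late embryogenesis genes 3 rose and 5 fell, including Solyc09g008770 (-1.54 ± 0.17) and Solyc02g077970 (-1.43 ± 0.10). Of 6 LBD genes 3 fell. Of 8 trichome and wound genes 2 rose and 1 fell, with proteinase inhibitor Solyc11g020960 at 1.87 ± 0.17 (block 0.40, not called), and of 21 epidermis genes 5 rose and 1 fell. Of auxin genes 3 of 25 rose, of SBP-box genes 2 of 9 and of vascular genes 1 of 20, and none of 7 gibberellin genes was called. In all 812 genes were higher and 243 lower of 10454, and 12 higher and 109 lower with plate as a random block. The excess of higher genes depended on plate 76 of uf. Without it 265 were higher and 328 lower, and 401 of these were called in the same direction in the full fit. Plate 77 of uf lay apart from plates 76 and 78 by 5033 genes, and the mean library score of uf was 0.495 ± 2.36 above that of WT.

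The s mutant, which makes highly branched inflorescences, was compared at 105 meristems with 336 of WT. S itself was lower, at -2.54 ± 0.22 (adjusted p = 2.2e-27) and LOB30 at -1.63 ± 0.22 (9.1e-12); both kept their call with the plate block (-2.51 and -1.85). PUCHI was lower, at -0.72 ± 0.20 (adjusted p = 0.00068), which the block did not call (-1.06). By stage PUCHI was at 37.6 CPM at TM1 and 38.8 at TM2, against 123 and 149 in WT, but at 92.3 against 51.9 at LTM and 116 against 52.1 at EFM (10 and 4 meristems of s). LOB30 was at 8.77 against 63.7 at TM1, 16.3 against 133 at TM2, 37.2 against 54.1 at LTM and 52.5 against 34.0 at EFM. SSP (0.91 ± 0.17) and MBP20 (0.73 ± 0.19) were higher without the block only, so 2 of 14 inflorescence regulators rose and 3 fell, the same when adjusted over the list alone (camera adjusted p = 0.895). Ferredoxin-NADP reductase Solyc12g062200, of photosynthetic electron transport, was at 1.98 CPM in s and 88.9 in WT (-5.51 ± 0.26, adjusted p = 5.2e-69); it was also at 2.02 and 5.51 CPM on WT plates 36 and 37. A phosphate-responsive protein (Solyc04g074450, -2.87 ± 0.20), an ethylene-responsive heat gene (Solyc04g011440, -2.34 ± 0.15) and a heavy metal gene (Solyc11g007200, -2.12 ± 0.19) were lower. In the list of heat shock and late embryogenesis genes 2 of 40 rose and 9 fell (camera adjusted p = 2.0e-06; adjusted p = 0.0562 with an estimated correlation), among them Solyc06g076020 (-2.49 ± 0.17) and Solyc08g078695 (-2.45 ± 0.17). Late embryogenesis proteins of the same list, Solyc06g009140 (-2.34 ± 0.23) and Solyc03g116390 (-2.32 ± 0.18), were lower too, the former without the block only; heat shock protein Solyc11g066100 was lower, at -1.97 ± 0.12.

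Genes higher in s included a NADH-ubiquinone oxidoreductase-like gene (Solyc02g092270, 1.60 ± 0.07), an IAA-amido synthetase that conjugates auxin (Solyc02g092820, 1.54 ± 0.10), a ubiquitin-conjugating enzyme (Solyc02g093110, 1.53 ± 0.09), a negative regulator (Solyc06g068620, 1.81 ± 0.11) and a maternal effect protein (Solyc01g108910, 1.73 ± 0.09). Of 6 LBD genes 1 rose (Solyc02g092550, 0.86 ± 0.09) and 3 fell (Solyc02g085910 by -2.25 ± 0.20), all 4 also with the block. Of 53 photosynthesis genes 9 rose, with Solyc03g005780 at 1.53 ± 0.18, and 1 fell, Solyc11g056320 at -1.5 ± 0.13 (camera adjusted p = 0.0864). Of 21 epidermis genes 7 fell, such as lipid-transfer protein Solyc10g075070 (-1.33 ± 0.14) and 3-ketoacyl-CoA synthase Solyc03g005320 (-1.10 ± 0.11), with camera adjusted p = 0.0665. Ribosomal proteins moved both ways (7 up and 5 down of 144), 3 of 61 histones and cyclins rose, and cytokinin genes gave 1 up and 1 down of 15, the latter LOG gene Solyc11g069570 (-1.82 ± 0.21, not with the block). TKN2 (-0.20 ± 0.04) and TM6 (0.25 ± 0.16) were not called. In all 321 genes were higher and 407 lower of 10039. With plate as a random block 133 were higher and 264 lower. The balance of directions moved with single plates of s: 733 higher and 470 lower without plate 60, and 161 and 387 without plate 62. The library score of s was -0.874 ± 1.27 against a WT mean of 0, and the 105 s meristems share a season with 133 of the WT meristems, against which 875 genes were called.

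The transient genes were then followed in each mutant at TM2, LTM and EFM, on WT meristems that had not been used to choose them. These could share plates with the meristems used for the choice, so differences between plates were not held out. Recorded ages of uf at these stages lay above those of WT, so plant age was not parted from genotype there. In uf, 92.2% of 77 transiently high genes were lower than in WT, with a median log2 fold change of -0.54 against -0.11 over all genes (63 uf and 72 WT meristems; camera adjusted p = 2.9e-16, and adjusted p = 0.00605 with an estimated correlation). With the median of all genes taken off they were at -0.43, and 3 random regroupings of plates, the real one included, were as large (highest other -0.52). Over all shared stages the median was -0.36 (adjusted p = 0.178 with an estimated correlation). The 17 transiently low genes were higher, with a median of 0.51 (adjusted p = 0.00343 with an estimated correlation); with the median of all genes taken off they were at 0.62, and 7 random regroupings were as large, the real one included (highest other 0.98). With the parts of WT exchanged the median was 0.36 (adjusted p = 0.114 with an estimated correlation). In s, 79.7% of 79 transiently high genes were lower, with a median of -0.47 against 0.03 (31 meristems; adjusted p = 2.2e-13, and adjusted p = 0.00605 with an estimated correlation). With the parts of WT exchanged the s median was -0.24, with 65.4% lower (adjusted p = 0.224 with an estimated correlation). In lob30_lob31 the medians were -0.22 for the high and 0.51 for the low genes (adjusted p = 0.463 and 5.1e-05; adjusted p = 0.76 and 0.065 with an estimated correlation). In puchi they were -1.23 and 0.88, around a median of -0.48 over all genes (adjusted p = 0.0321 and 0.00383; adjusted p = 0.407 and 0.14 with an estimated correlation). In puchi_lob30_lob31 they were -0.94 and 0.93, around -0.51 (adjusted p = 0.0908 and 0.000429; adjusted p = 0.486 and 0.065 with an estimated correlation). At the early stages VM, TM0 and TM1 the high genes were at -0.22 in uf and 0.05 in s.

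**Figure D3:**
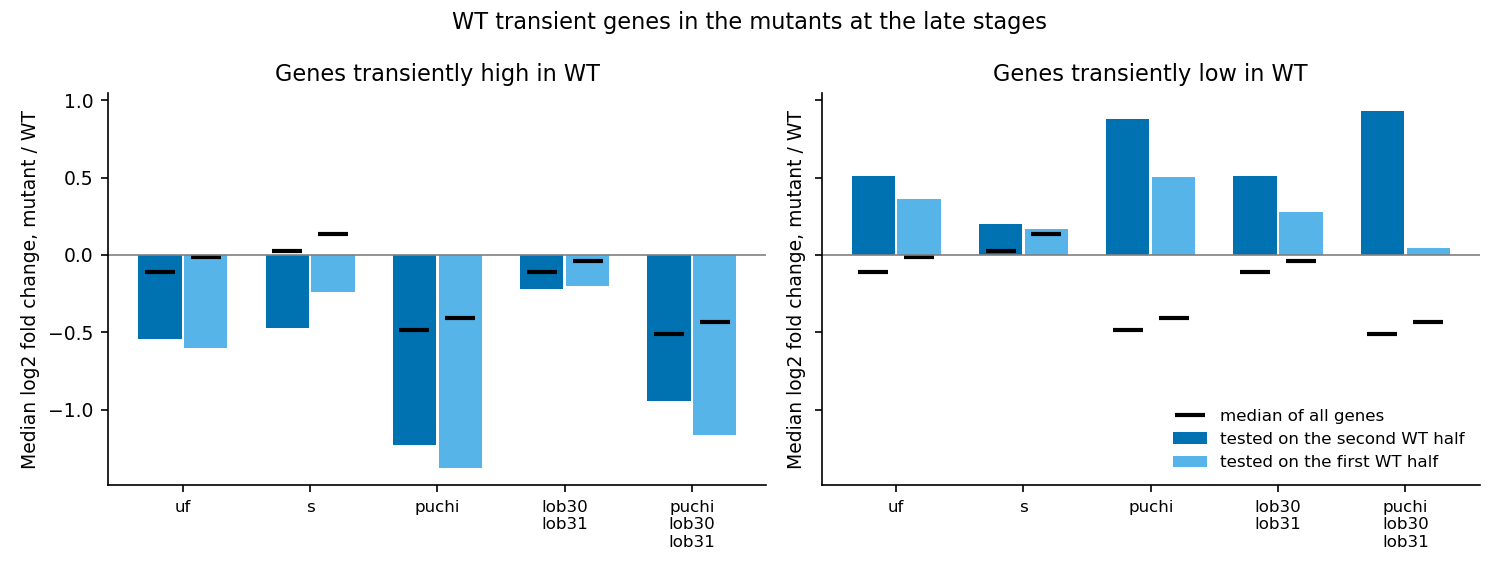
Median log2 fold change, mutant against WT at TM2, LTM and EFM, of genes transiently high or low in WT; bars are tests on each of 2 random parts of WT, and a black dash is the median of all genes. In uf the transiently high genes lie at -0.54 against -0.11 for all genes.

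Meristems of puchi (84 against 328 of WT) ask what the AP2 factor contributes. PUCHI was lower, at -5.94 ± 0.56 (adjusted p = 1.1e-22; block -3.56, called), and LOB30 was at -0.49 ± 0.26, not called (adjusted p = 0.064). By stage LOB30 was at 9.24 CPM at TM1 and 25.3 at TM2, against 63.7 and 133 in WT, and at 56.7 against 54.1 at LTM and 64.3 against 34.0 at EFM. FUL2 (-2.98 ± 0.26) was lower and TMF (1.12 ± 0.09) and TKN1, a KNOX factor of the meristem (1.40 ± 0.06), were higher, each also with the block. FUL1 (-2.49 ± 0.19), FA (0.79 ± 0.05) and TKN2 (-0.71 ± 0.07), named after their values were seen, kept their calls with the block as well. MBP20 (-3.07 ± 0.51) and S (-2.52 ± 0.41) were called without the block only. In the inflorescence list 3 of 14 rose and 8 fell (camera adjusted p = 0.764), and of 8 meristem genes 3 rose and 4 fell, with LYR at -3.22 ± 0.40 (not with the block), FAB at -2.14 ± 0.23 and GOB, the GOBLET boundary factor, at -1.73 ± 0.11. TM5 (-2.90 ± 0.42) and TM6 (-2.70 ± 0.49, not with the block) were lower. These calls stand in a library set that differs from WT in its whole profile: the library score of puchi was 3.99 ± 0.925 where the highest WT meristem reached 4.73. The mean score of WT plate 56 was 3.22, and the next highest WT plate mean was 0.905 (plate 28). Fits of puchi with the score as a covariate therefore rest on a small overlap, mostly with the plate that defined the score. With the score as a covariate PUCHI was at -7.39, LOB30 at -1.88 and GOB at -1.24, all called, while FUL2 (-0.33), TMF (0.24) and FA (0.14) were not. MBP20 (2.34, adjusted p = 0.00105) and TM6 (2.02, adjusted p = 0.0034) turned to the opposite direction and were called in it. With the transcriptome score in place of stage FUL2 turned to 1.24 (adjusted p = 0.00327, called) and FUL1 to 0.48, not called. That fit has no stage term, and its score follows the library score, so it is not a separate check.

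Gene families moved widely in puchi. Of 143 ribosomal protein genes 8 rose and 82 fell (camera adjusted p = 0.000887; adjusted p = 0.715 with an estimated correlation), for example Solyc06g007210 (-5.29 ± 0.45), Solyc04g074910 (-5.26 ± 0.28) and Solyc12g010350 (-5.25 ± 0.40); with the library score as a covariate 5 rose and 96 fell, and these examples were at 0.87, -1.45 and 0.59. Of 51 photosynthesis genes 12 rose and 22 fell, with photosystem subunits Solyc05g025600 (-5.15 ± 0.47) and Solyc04g011370 (-4.82 ± 0.35), and of 59 histones and cyclins 10 rose and 19 fell, with histone H2B Solyc11g066430 (-3.48 ± 0.33) and histone H4 Solyc11g072840 (-3.04 ± 0.15). With the library score the histones were at 0.80 (adjusted p = 0.0132, called) and -1.71, called, and the photosystem subunits at -0.35, not called, and -0.88, called; with the transcriptome score in place of stage these subunits were at 0.23 and 0.40, not called. All 7 gibberellin genes were lower (Solyc06g069790 by -4.31 ± 0.31, at 0.21 with the score), as were 12 of 21 auxin genes against 2 higher (Auxin Response Factor Solyc01g103050 by -3.10 ± 0.21). Cytokinin genes gave 5 up and 8 down of 13 (LOG gene Solyc09g007830 by -3.52 ± 0.36), LBD genes 3 up and 2 down of 6 (Solyc01g091400 by -2.73 ± 0.19), SBP-box genes 3 up and 4 down of 8 (Solyc01g090730 1.57 ± 0.14, Solyc03g044080 -1.19 ± 0.07), heat shock genes 12 up and 14 down of 40, epidermis genes 6 up and 10 down of 20, vascular genes 5 up and 4 down of 17, and trichome genes 4 down of 7. None of these lists after the ribosomal one had a camera adjusted p under 0.239. Camera's direction was upward for photosynthesis (median -0.19) and inflorescence genes (median -0.99), although more of their members fell and the latter median lies below that of all genes (-0.66), and the histone median was 0.26. Highest were NAD(P)H-quinone oxidoreductase Solyc02g063080 (3.32 ± 0.14), glycine-rich protein Solyc09g092700 (2.83 ± 0.18), a WD40 repeat protein (Solyc09g092740, 2.69 ± 0.21), beta-amylase Solyc08g077530 (2.29 ± 0.17) and a 50S ribosomal protein (Solyc06g009985, 2.27 ± 0.10). Ferredoxin-NADP reductase Solyc12g062200 was lower, at -5.46 ± 0.44. In all 1890 genes were higher and 4713 lower of 9148, with a median over all genes of -0.66. Outside the score's own genes 6289 were called without the score and 4476 with it, 2836 of them shared.

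**Figure D4:**
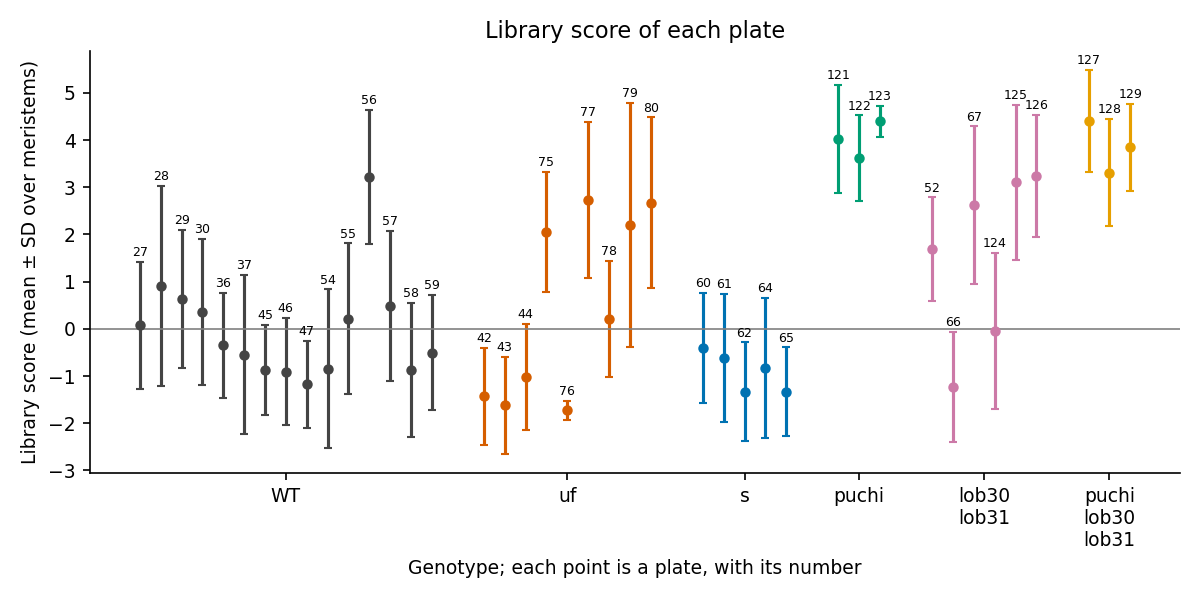
Library score per plate (log2 units; mean with SD over meristems), by genotype. The plate means of puchi run from 3.62 to 4.40, and that of WT plate 56, the highest of WT, is 3.22.

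In lob30_lob31 (168 against 376 of WT), S was lower, at -1.41 ± 0.20 (adjusted p = 1.3e-11; block -1.62, called) and TMF higher by 0.87 ± 0.08. PUCHI (0.05 ± 0.17) and LOB30 (-0.05 ± 0.17) did not differ by a called amount. FUL2 was lower, at -0.64 ± 0.14 (block -1.31), and MBP20 (-0.68 ± 0.20), TM6 (-0.91 ± 0.18) and LYR (-0.83 ± 0.14) without the block only. With the library score MBP20 was at 0.43 (adjusted p = 0.015) and TM6 at 0.093, and FUL2 was at 0.048 in season 3 alone, none of them called. Of 14 inflorescence regulators 1 rose and 3 fell. A DNA polymerase (Solyc05g009490, 3.54 ± 0.11), a flavin-binding kelch protein of the light-clock family (Solyc01g005300, 2.77 ± 0.09), Solyc05g009520 (2.15 ± 0.10), the maternal effect protein Solyc01g108910 (2.10 ± 0.09), a thiamine thiazole gene (Solyc07g064160, 1.89 ± 0.08) and metallothionein Solyc06g076140 (1.62 ± 0.09) were higher. On the plates of the later round alone Solyc05g009520 was at -0.79 and Solyc01g108910 at -0.072, and Solyc05g009490 averaged 1.41 to 2.17 CPM there. Of 143 ribosomal protein genes 42 fell (camera adjusted p = 0.00788; adjusted p = 0.761 with an estimated correlation), such as Solyc07g042840 (-1.98 ± 0.10); with the library score as a covariate 2 rose and 8 fell. A mitochondrial import gene (Solyc01g109220, -2.24 ± 0.18), ribosomal protein Solyc11g040220 (-2.03 ± 0.14) and heat shock protein Solyc06g036290 (-1.84 ± 0.16) were lower. Of 52 photosynthesis genes 10 rose and 7 fell (camera adjusted p = 0.00569; adjusted p = 0.614 with an estimated correlation), with Solyc03g005770 at 1.14 ± 0.09 and Solyc06g082940 at 1.09 ± 0.08. Of 59 histones and cyclins 5 fell although their median was 0.14 (camera adjusted p = 0.00592, upwards; adjusted p = 0.761 with an estimated correlation). LBD genes Solyc03g112430 (1.16 ± 0.10) and Solyc01g091400 (0.66 ± 0.10, not with the block) rose, AUX/IAA gene Solyc01g097290 rose (1.17 ± 0.09) while 6 of 22 auxin genes fell, LOG genes Solyc09g007830 (-1.42 ± 0.13) and Solyc10g082020 (-1.10 ± 0.11) and gibberellin 2-oxidase Solyc01g058030 (-1.28 ± 0.10) fell, and SBP genes Solyc10g018780 (1.46 ± 0.11) and Solyc01g090730 (1.35 ± 0.09) rose. In all 315 genes were higher and 1990 lower of 9392, against 1266 with plate as a random block. The library score was 1.58 ± 2.19, and outside its own genes 297 higher and 1828 lower genes were called without it as a covariate (2125 in all) and 247 higher and 195 lower with it (442). The called number also moved with the plates used: 4492 in the earliest season, 492 in the next, and 4077 with plates 124 to 126 alone. Recorded ages reached 24 days in lob30_lob31 and 12 in WT. Age was not a covariate, so these counts do not part genotype from plant age.

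In puchi_lob30_lob31 (80 against 328 of WT), PUCHI was lower, at -6.30 ± 0.61 (adjusted p = 8.7e-22) and LOB30 at -2.81 ± 0.36 (9.0e-14), both also with the block (-3.70 and -2.08) and with the library score (-7.63 and -4.14). FUL2 (-2.65 ± 0.24) was lower, and TMF (1.19 ± 0.10) and TKN1 (1.13 ± 0.07) higher. FUL1 (-2.44 ± 0.19) is named after its value was seen. With the transcriptome score in place of stage, a fit without a stage term, FUL2 turned to 0.77 (adjusted p = 0.0447, called) and FUL1 to 0.15, not called. With the library score FUL2 (-0.29) and TMF (0.28) were not called and FUL1 (-0.89) was. MBP20 (-3.59 ± 0.59), S (-2.57 ± 0.42) and LYR (-2.77 ± 0.38) were lower without the block only; with the library score MBP20 was at 1.29 (adjusted p = 0.136), not called. GOB was lower, at -1.27 ± 0.11 and TM5 at -2.60 ± 0.38. Of 14 inflorescence regulators 2 rose and 9 fell. A glycine-rich protein (Solyc06g061200, 5.55 ± 0.25), a methanol-inducible protein (Solyc08g082120, 4.12 ± 0.23), a calcium-dependent lipid-binding protein (Solyc06g036110, 3.44 ± 0.15), Solyc02g063080 (3.38 ± 0.14), beta-amylase Solyc08g077530 (3.20 ± 0.16), calreticulin Solyc04g048900 (2.57 ± 0.18) and glutamate decarboxylase Solyc11g011920 (2.51 ± 0.14) were higher. Solyc12g062200 was lower, at -6.10 ± 0.53 and AUREA, the phytochromobilin synthase of phytochrome (Solyc01g008930), at -4.71 ± 0.41. Of 143 ribosomal protein genes 8 rose and 77 fell (Solyc04g074910 -4.74 ± 0.29 and Solyc12g010350 -4.72 ± 0.41; camera adjusted p = 0.000157; adjusted p = 0.614 with an estimated correlation), and 8 rose and 93 fell with the library score. All 7 gibberellin genes were lower (Solyc06g069790 by -3.78 ± 0.32, at 0.50 with the score, not called), as were 14 of 21 auxin genes against 2 higher, while photosynthesis genes gave 14 up and 20 down of 52, histones 15 up and 14 down of 59 and heat shock genes 8 up and 14 down of 40 (Solyc06g036290 by -4.29 ± 0.31). LBD gene Solyc01g091400 was lower, at -2.18 ± 0.18 and SBP gene Solyc01g090730 higher by 2.01 ± 0.14. In all 1758 genes were higher and 4408 lower of 9246, the library score was 3.86 ± 1.12, and outside its own genes 5842 were called without and 3996 with it. As for puchi, the fits with the score rest on a small overlap with WT.

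The triple mutant was also set against mutants of the same processing round. Against lob30_lob31 (80 and 75 meristems), PUCHI was lower, at -6.21 ± 0.56 (adjusted p = 3.6e-17) and LOB30 at -3.18 ± 0.31 (1.0e-17), and both kept their call with the plate block (-4.74 and -3.02). Glycine-rich protein Solyc09g092700 (2.74 ± 0.31) and enolase Solyc03g114500, of glycolysis (2.13 ± 0.12), were higher, and Solyc12g062200 (-6.34 ± 0.19), a pectinesterase in a shared row (Solyc02g080200, -2.71 ± 0.23) and the asparaginase gene Solyc04g078460 (-2.05 ± 0.20) lower, all with the block too. FUL2 (-1.72 ± 0.30) and FUL1 (-1.42 ± 0.25) were among 4 lower of 7 inflorescence regulators, BOP1 was higher (0.92 ± 0.21) and GOB lower (-0.71 ± 0.19), and 2 of 128 ribosomal protein genes rose and 57 fell, such as Solyc06g007220 (-3.55 ± 0.44; camera adjusted p = 5.8e-06, and adjusted p = 0.45 with an estimated correlation). Photosynthesis gene Solyc04g011370 (-3.20 ± 0.37) and LBD gene Solyc01g091400 (-2.61 ± 0.26) were lower. With the library score FUL2 was at 0.51 and FUL1 at 0.015, not called, and outside the score's genes 364 higher and 837 lower genes became 319 and 57. None of FUL1, FUL2, BOP1, GOB and these 3 genes was called with the block, which called 9 of the 1409 genes of the edgeR test. Against puchi (80 and 84 meristems), LOB30 was lower, at -1.97 ± 0.24 (adjusted p = 1.5e-12; block -0.87, not called). Enolase Solyc03g114500 was higher by 1.85 ± 0.10 and a nuclear transport gene (Solyc02g066830) lower, at -1.82 ± 0.12, the 2 genes called with the block. Of 29 photosynthesis genes 6 rose, with Solyc03g005780 at 1.48 ± 0.17 and Solyc03g005770 at 1.06 ± 0.16 (camera adjusted p = 0.000334; adjusted p = 0.271 with an estimated correlation), and of 22 heat shock genes 2 fell, with Solyc11g066100 at -1.67 ± 0.14 (camera adjusted p = 0.0113; adjusted p = 0.152 with an estimated correlation). In the LBD family LOB30 was the 1 called of 4 (camera adjusted p = 0.0383; adjusted p = 0.386 with an estimated correlation). Ribosomal protein Solyc10g061970 (-1.46 ± 0.13), lipid-transfer protein Solyc10g075070 (-1.34 ± 0.20) and SAUR gene Solyc12g036415 (-0.87 ± 0.16) were lower. In all 80 genes were higher and 37 lower of 3946.

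**Figure D5:**
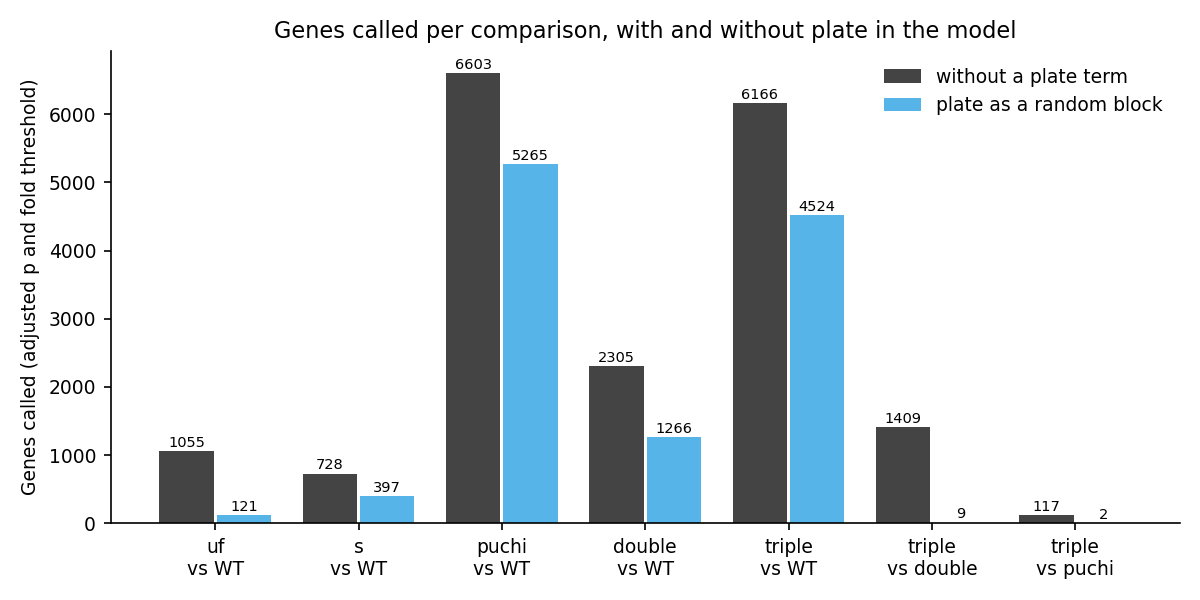
Total genes called, both directions together, per genotype comparison by edgeR on meristems and with plate as a random block. The edgeR bar for puchi against WT is 6603, made up of 1890 higher and 4713 lower. The block called 1931 higher and 3334 lower.

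Effects shared between mutants were counted as genes called in the same direction against WT. In uf and s, 140 genes moved together and 22 apart, where independent lists would share 24.8; with calls that also hold in the plate block 51 moved together and none apart, where 2.39 would. The covariance of the fold changes was 0.0238, against 0.00041 for simulated unchanged groups, which carry no plate differences; exchanging real plates called a median of 536 genes for uf and 196.5 for s. With WT split between the comparisons 126 genes were shared. In puchi and puchi_lob30_lob31, 5791 genes moved together (independent lists 2592, covariance 1.96, simulated 0.000442, WT split 4800). These genotypes share a processing round, with library scores of 3.99 and 3.86. The puchi_lob30_lob31 profile followed the difference of WT plate 56 from plates 55 and 57 to 59 (Spearman 0.856), so shared genotype and shared plate differences are not parted. In puchi and lob30_lob31, 2074 moved together (independent lists 1044, covariance 0.566, simulated 0.000179, WT split 1678.5). Both profiles followed the difference between WT plate 56 and plates 55 and 57 to 59 (Spearman 0.846 and 0.811), and with the library score 13.1% of the lob30_lob31 calls remained. In s and puchi, 131 moved together and 350 apart (independent lists 253, covariance -0.269, simulated 0.000214), and with calls that also hold in the plate block 50 together and 95 apart. The s profile ran against the same WT plate difference (Spearman -0.689) that puchi followed. A dependence of the mutant effect on early (VM, TM0, TM1) against late stages was called for 780 genes in uf, 152 in s, 54 in puchi, 169 in lob30_lob31 and 45 in puchi_lob30_lob31; with plate as a random block the counts were 65, 21, 18, 11 and 32.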

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

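The regroupings of plates were planned. The predictions for the regroupings of WT stages were written only after the results had been seen. The tests of library score, season, depth and processing round were also chosen after that. Among the mutant groups with 5 to 9 plates, 33 sets of plate values were searched for a plate far from the others, and 3 were picked out; chance alone picks out about 1 in 20 groups. PUCHI averaged 26.3 CPM on plate 80 of uf, where the next highest plate had 13.0 and the lowest 0.0984. The DNA polymerase gene Solyc05g009490 averaged 10.1 CPM on the same uf plate, against 6.36 on the next. S averaged 9.68 CPM on plate 66 of lob30_lob31, against 3.28 on the next. The effect of the mutation differed between early and late stages for 780 genes in uf, 152 in s, 54 in puchi, 169 in lob30_lob31 and 45 in puchi_lob30_lob31 (edgeR interaction term). When whole plates were exchanged between the genotypes, 14 of 25 groupings, the real one included, called at least as many stage dependent genes for uf (highest other 3555), 14 for s (3182), 9 for puchi (3296), 12 for lob30_lob31 (2310) and 7 for puchi_lob30_lob31 (3332). These counts therefore lie within what groupings of plates give, and by-stage values of PUCHI and LOB30 carry no test of their own.

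The WT steps were set against groupings in which stages were exchanged among the meristems of a plate. Of 41 groupings, the real one included, 5 called at least as many genes for VM to TM0 (highest other 877), 3 for TM0 to TM1 (242), 4 for TM1 to TM2 (571), 6 for TM2 to LTM (698), 5 for LTM to EFM (1577) and 3 for EFM to FM (1567). For the transiently high genes only the real grouping, 1 of 41, gave 92 genes, and the highest other gave 33. For the transiently low genes 6 of 41 gave at least 38 (highest other 253). In the transient genes, PUCHI and LOB30 therefore belong to a set whose number exchanged stages did not give, while the number of genes at each separate step was also given by exchanged stages.

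Most genes called in puchi and puchi_lob30_lob31 were lower than in WT, and weighed first is whether this is a difference between plates that also occurs inside a genotype. The fold changes of puchi followed those between WT plate 56 and the other WT plates of its season (Spearman 0.846), so the shape of the change is found inside WT; it could come from plant state or from library preparation. With the library score as a covariate 45.1% of 6289 calls kept direction and call, in a fit with a small overlap in score with WT. Against lob30_lob31 of the same processing round 58.6% did, of the 3192 puchi calls also tested there. With the score added it was 19.9% of 3349 calls, below the lower bound. Calls on genes left untested in that round are not covered. So neither the plate difference nor the puchi genotype can be taken as the whole of it. Fewer UMIs per meristem are argued against as the whole, in a linear fit: with log2 of total UMIs as a covariate, which 1617 genes followed in the puchi fit, 95.7% of the lower calls of puchi and 95.0% of those of puchi_lob30_lob31 stayed. Only 12 of 328 WT meristems had a total at or below the puchi median, so the fit rests on a small overlap. As a part, fewer UMIs cannot be told apart: the correlation with shallow against deep WT was 0.246, between the bounds of 0.2 and 0.5 written before this test was run, 66.1% of the puchi calls had the same sign there, and 58 of the 64 genes called in both had the opposite one. Exchanging whole plates gave at most 2704 genes for puchi and 2300 for puchi_lob30_lob31, and 1 of 25 groupings, the real one, reached the observed counts in each.

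In lob30_lob31 most called genes were lower too, and 13.1% of the calls remained with the library score as a covariate, so the difference between plates may account for most of them. The real grouping of plates was 1 of 25 to reach 2305 genes, and the highest other, 2245, put plates 52 and 125 with WT plates 28, 30, 37 and 56. In WT the 457 calls from VM to TM0, 399 of them lower, were kept at 9.19% with the library score and 11.8% with plate as a fixed block. These fits called 15 and 18 lower genes, but both also take out stage differences that run along with plates. The step called 5 genes without plate 54, 2 in the summer of 2019 and 1794 in season 3. So the stage itself was not shown to be the source of most of the lower ones, nor could it be told apart from plate. PUCHI and LOB30 rose at this step in both of these fits, but with plate as a random block neither was called (log2 fold changes 1.00 for PUCHI and 0.40 for LOB30), nor with limma voom (1.28 and 0.89).

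The uf calls were weighed by season. Across genes called in either season, the fold changes of uf plates of the summer of 2019 and of the later season had a Spearman correlation of 0.0872, and 13.6% of the calls of 2019 were called in the same direction later, so the uf genotype could be the source of only a part in this fit. With the library score as a covariate the correlation was 0.305 and 38.2% were called in the same direction, at which neither season or plate nor genotype can be refused. The later uf plates were set against WT of another season, so season and genotype are not apart there. Exchanging whole plates gave at least 1055 genes in 4 of 25 groupings (highest other 1770, with uf plates 44, 77 and 79 beside WT plates 27, 29, 36, 45, 56 and 57), which is structure among the plates. S, LOB30, PUCHI and FUL1 were called lower with plate as a random block as well. For s, 3 of 25 groupings of plates reached 728 genes, and the highest other, 3578, set WT plates 27, 28, 55, 56 and 57 apart.

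For the comparisons within a processing round, meristems were exchanged within stage. Against lob30_lob31 the real grouping was 1 of 25 to reach 1409 genes (highest other 60), and against puchi 1 of 25 to reach 117 (highest other 38). When whole plates were exchanged instead, 3 of 10 groupings reached 1409 (highest other 1527) and 8 of 10 reached 117 (highest other 1570). The plates of these mutants thus differ by as many genes as the genotypes do.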

How the results depend on the processing

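Genotype is nested in plate, and the meristem is the replicate, so plate differences enter each genotype count. With plate as a random block (limma voom) 12 higher and 109 lower genes (1.2e+02 in all) were called for uf instead of 1055, 397 for s instead of 728, 1266 for lob30_lob31 instead of 2305, 9 for puchi_lob30_lob31 against lob30_lob31 instead of 1409 and 2 against puchi instead of 117. The stage dependent genes were 65 in uf, 21 in s, 18 in puchi and 11 in lob30_lob31 with that block, instead of 780, 152, 54 and 169. In WT it gave 6 genes for VM to TM0 instead of 457, 75 for TM0 to TM1 instead of 125, 147 for TM1 to TM2 instead of 221 and 223 for EFM to FM instead of 661, and 61 transiently high genes instead of 92. Limma voom without the block gave 15 for VM to TM0, 81 for TM0 to TM1 and 97 for LTM to EFM instead of 217. With plate as a fixed block the counts were 61 for VM to TM0, 175 for TM2 to LTM instead of 93, 705 for LTM to EFM and 260 for EFM to FM. The causes of the changes in this part were not tested unless one is given. The fits by season or by set of plates, those with a library score, the early stages and the random block in WT were chosen after the data had been seen.

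Without the fold threshold, which by construction adds small changes, the counts were 6555 for uf, 6077 for s, 7288 for lob30_lob31, 3119 for puchi_lob30_lob31 against lob30_lob31, 718 against puchi, 257 for TM0 to TM1, 355 for LTM to EFM and 2215 for EFM to FM, with 319 transiently high and 217 transiently low genes. Without the expression filter they were 3696 for uf, 2131 for s, 11786 for puchi instead of 6603, 5081 for lob30_lob31, 10821 for puchi_lob30_lob31 instead of 6166, 4879 and 449 for it against lob30_lob31 and puchi, 609 for LTM to EFM and 1490 for EFM to FM, with 181 transiently high and 92 transiently low genes instead of 38. With LTM alone as the middle stage 65 genes were transiently low. Sums per plate and stage gave 1659 (edgeR) and 1725 (DESeq2) for uf, 1096 (edgeR) for s, and 2344 (edgeR) and 2419 (DESeq2) for puchi_lob30_lob31 against lob30_lob31. In the DESeq2 sums Solyc11g020960 in uf changed sign, to -0.37.

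By season, uf gave 1629 genes in the summer of 2019 and 2061 on plates 75 to 80, and lob30_lob31 gave 4492 in the summer of 2019, 492 in season 3 and 4077 on its plates of the later round. VM to TM0 gave 2 genes in the summer of 2019 and 1794 in season 3. In season 3 TM1 to TM2 gave 1535, TM2 to LTM 9, LTM to EFM 31, EFM to FM 139 and the transiently high set 59; TM2 to LTM gave 256 in the summer of 2019. Signs changed in the summer of 2019 for Solyc03g005470 (-0.75), Solyc09g065590 (-0.093) and Solyc03g005780 (-0.044) in uf. In season 3 they changed for MBP20 (0.20) and FUL2 (0.048) in lob30_lob31 and for Solyc06g007180 (-0.10) from TM2 to LTM. On the plates of the later round they changed for Solyc05g009520 (-0.79) and Solyc01g108910 (-0.072) in lob30_lob31.

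With the transcriptome score in place of stage, 3505 genes were called for puchi, 422 for lob30_lob31 and 3145 for puchi_lob30_lob31. These fits have no stage term, and the score followed the library score and not the order of stages. Signs changed in puchi for S (0.13), FUL1 (0.48), FUL2 (1.24), FAB (0.30), Solyc04g074910 (0.27), Solyc05g025600 (0.23), Solyc04g011370 (0.40) and Solyc06g069790 (0.98). They changed in lob30_lob31 for MBP20 (0.40) and FUL2 (0.13), in puchi_lob30_lob31 for FUL1 (0.15), FUL2 (0.77) and Solyc06g069790 (0.66), and against lob30_lob31 for FUL1 (0.043) and FUL2 (0.29). With the library score as a covariate VM to TM0 gave 55 genes and LTM to EFM 132. Outside the genes of the score, lob30_lob31 then gave 442 genes instead of 2125, and puchi_lob30_lob31 against lob30_lob31 376 instead of 1201. Signs changed with it in puchi for MBP20 (2.34), TM6 (2.02), Solyc06g007210 (0.87), Solyc12g010350 (0.59), Solyc11g066430 (0.80) and Solyc06g069790 (0.21), and in lob30_lob31 for MBP20 (0.43) and TM6 (0.093). They also changed in puchi_lob30_lob31 for MBP20 (1.29), Solyc12g010350 (0.57) and Solyc06g069790 (0.50), and against lob30_lob31 for FUL1 (0.015), FUL2 (0.51) and Solyc06g007220 (0.14).

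For the transient sets in the mutants, the high set in s had a median of 0.051 at early stages (adjusted p = 0.308). The low set in s had 0.14 with plate as a random block (adjusted p = 0.0719), 0.17 with the random parts of WT exchanged (adjusted p = 0.738), 0.087 over all stages (adjusted p = 0.828) and 0.060, reversed against the median of all genes, at early stages (adjusted p = 0.546). In puchi the high set had -1.37 with the parts of WT exchanged (adjusted p = 0.0808), -0.98 over all stages (adjusted p = 0.342) and -0.56 early (adjusted p = 0.503), and the low set 0.51 exchanged (adjusted p = 0.255). The low set in lob30_lob31 had 0.28 exchanged (adjusted p = 0.117) and 0.10 early (adjusted p = 0.115), and in puchi_lob30_lob31 0.044 exchanged (adjusted p = 0.470). With an estimated correlation between genes the medians stayed and the adjusted p rose: 0.308 for the low set in s (0.20), 0.407 for the high set in puchi (-1.23), 0.140 for the low set there (0.88), and 0.0650 for the low sets in lob30_lob31 (0.51) and puchi_lob30_lob31 (0.93).

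Leaving out 1 plate at a time gave 593 (without plate 76) to 1308 genes for uf, 548 to 1203 (without 60) for s, 5893 to 7143 for puchi, 1621 to 3541 (without 66) for lob30_lob31 and 5608 to 6527 for puchi_lob30_lob31. The latter gave 621 (without 124) to 1843 against lob30_lob31 and 94 to 858 (without 122) against puchi, where leaving out plate 127 or the lowest numbered puchi plate also moved the count. VM to TM0 ranged from 5 (without 54) to 701 (without 45) and also moved without 47, 55, 56 or 57. TM0 to TM1 ranged from 96 to 140, TM1 to TM2 from 161 to 373 (without 28), TM2 to LTM from 68 to 273 (without 58), LTM to EFM from 106 (without 37) to 608 (without 58; also moved without 27 or 46) and EFM to FM from 435 (without 36) to 972. The transient sets ranged from 81 to 106 and from 31 to 45. Calls lost without 1 plate were J, CLV3, Solyc01g107730 and Solyc11g020960 in uf (76), MBP20 (62), PUCHI (56 or 64) and Solyc03g005780 (60) in s, and TKN2 in puchi (123), where LOB30 was called instead. In lob30_lob31 they were MBP20 (52, 58 or 67), FUL2 (52, 67, 125 or 126), TM6 (52) and Solyc01g091400 (66 or 124). Against lob30_lob31 they were FUL1 and FUL2 (124) and GOB (124 or 127), and against puchi Solyc12g036415 (122). Without plate 54 each named call from VM to TM0 was lost except that of Solyc10g074440, which was lost without 28. Other WT calls that depended on 1 plate were MBP20, S, CLV3 and FAB from TM0 to TM1, LOB30 and Solyc09g018010 to TM2, BOP1 and BOP2 to LTM, S, MBP20, J, LYR and Solyc03g005780 to EFM, and TM6 and Solyc07g063600 to FM.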

Other observations

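Apart from the fixed lists, the tests in this part were chosen only after their results had been seen. In s, the calls that hold in both fits gathered on chromosome 2, which carries S. Of 357 such genes 77 (21.6%) lie there, against 10.3% of the genes tested (ratio 2.10, Fisher p = 1.9e-10, adjusted p = 2.8e-08). They were densest toward the end of the chromosome: 48 of 204 genes with identifier numbers from 90000 to 99999 were called, against 3.14% of genes elsewhere, while 4 of 186 were called among numbers 70000 to 79999, where S lies. The NADH-ubiquinone oxidoreductase-like gene Solyc02g092270, the IAA-amido synthetase Solyc02g092820, the ubiquitin-conjugating enzyme Solyc02g093110 and the LBD gene Solyc02g092550, all higher in s, are in this part. The ratio of 2.10 passed the bound written for a chromosome segment near S that differs between the lines, but it covers the whole chromosome. The numbers around S were not dense in calls, so linkage to S itself is not shown. A differing segment toward the end of the chromosome was not tested, and these genes may differ through it rather than through S.

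In lob30_lob31, 1990 of 9392 genes tested, and of all 2305 called, were lower. Calls in further fixed lists were gibberellin genes 3 of 7 lower and trichome and wound genes 3 of 7 lower. Heat shock genes were 8 of 40 lower, near the share of all genes. Cytokinin genes were 1 higher and 3 lower of 15, and epidermis and cuticle genes 1 higher and 3 lower of 20. In puchi_lob30_lob31, 4408 of 9246 genes tested were lower. Cytokinin genes went both ways there, 5 higher and 6 lower of 14, as did vascular and cell wall genes, 5 higher and 5 lower of 16. Epidermis and cuticle genes there were 5 higher and 10 lower of 20, meristem and boundary genes 3 higher and 4 lower of 8, and SBP-box genes 2 higher and 4 lower of 8. Apart from the vascular list, the lower members of these lists lay near the share of all genes. Against lob30_lob31, where 1409 of 4835 genes tested were called, 3 of 3 gibberellin genes and 5 of 25 heat shock genes were lower in puchi_lob30_lob31. There 3 of 7 epidermis and cuticle genes were higher. In s, where 728 of 10039 genes tested were called, 1 of 7 gibberellin genes was higher. There 1 of 16 vascular and cell wall genes and 1 of 8 SBP-box genes were lower.

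Ferredoxin-NADP reductase Solyc12g062200 was nearly absent from whole plates. It averaged 1.40 to 3.15 CPM on the plates of s, 0.957 to 2.61 in puchi and 0.450 to 3.65 in puchi_lob30_lob31, and 103 to 197 in lob30_lob31. Among WT plates it was at 2.02 CPM on plate 36 and 5.51 on plate 37.

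Plates 52, 66 and 67 of lob30_lob31, whose meristems are labelled lob30 alone, differed from plates 124 to 126. DNA polymerase Solyc05g009490 averaged 109, 77.3 and 112 CPM on the former and 2.17, 1.41 and 2.13 on the latter, and enolase Solyc03g114500 averaged 282, 323 and 267 against 89.5, 49.5 and 72.7. Enolase was at 183 to 363 CPM on the plates of puchi_lob30_lob31. In all 35 genes set these plates apart, 29 of them higher on 52, 66 and 67. Splitting the 6 plates into 52, 66 and 124 against 67, 125 and 126 set 33 apart, and the remaining splits 0 to 9. That split also parts the plates by mean library score, 1.69, -1.24 and -0.051 against 2.62, 3.11 and 3.24. Differences between plates other than the label may therefore give such a number, but most splits did not. Of the 29 genes, 55.2% were above all 15 WT plates, at which a season effect can be neither taken nor refused. The lob30_lob31 results therefore join plates that could differ in more than the mutated genes, and plants with recorded ages from 9 to 24 days.

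In the 5 lob30_lob31 meristems with no stage, PUCHI averaged 127 ± 221 CPM and LOB30 69 ± 73.5 (SD).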
